A study of Homo sapiens with 9 samples.

How the data were processed

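RNA was measured in PANC-1 cells, an established line from a human pancreatic ductal carcinoma. The 9 libraries fall into 3 groups of 3: control, cobalt chloride (CoCl2, 200 µM for 48 h) and CoCl2 together with acriflavine (ACF, 2.5 µM for 48 h). The labels give no treatment for controls while their treatment protocol speaks of vehicle, so it is unclear whether controls received the vehicle. Per the labels' protocols, all cells were first kept for 24 h in medium with 1% serum, poly-A RNA was selected with oligo-dT beads, and stranded libraries were sequenced. The series' design text calls the replicates of each condition biological. No group analysed here received acriflavine alone, so an effect of acriflavine is always an effect on top of CoCl2.

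The authors deposited raw read counts per Ensembl gene ID, with 1 column per library and no normalization. The submitters' processing notes name cutadapt 1.7.1, Bowtie2 2.2.4, TopHat2 2.0.13, SAMtools 1.1, Cufflinks 2.1.1, bedtools 2.17.0 and featureCounts 1.4.6, with build GRCh37 and no order of steps. The annotation release and the strand setting of the counting are not given in the sources used here. Values of overlapping and antisense genes are therefore uncertain, as are those of genes with near-identical copies such as BNIP3, XPOT, KRT81, the metallothioneins and the histone genes. The table holds 63152 gene IDs, of which 51662 were given a symbol from a table of Ensembl gene names and 34553 had no count in any library. Of the 559 different genes on the lists, 557 matched an ID. Library totals ran from 13286339 to 15932220 counts. With no count in a library, a gene could still have a level of up to 0.188 to 0.226 CPM, the count scaled to a common library size, at a floor of 3 counts per library, which covers counting error only.

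Everything below was computed from those counts in R 4.3.3. Genes were kept by the filterByExpr function of edgeR 4.0.16 with a minimum count of 10, which left 16143. Libraries were scaled by TMM, and group differences were tested with the quasi-likelihood F test of edgeR over all 9 libraries, which share 1 estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of F. Levels are TMM-scaled CPM, given as mean ± SD of 3 libraries. The 3 comparisons were CoCl2 against control, CoCl2 with acriflavine against CoCl2, and CoCl2 with acriflavine against control. They were followed by a test for any difference among the 3 groups.

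The 23 gene lists and 5 lists of markers of other cell types were fixed before the data were examined, as were the tests and the rule for named genes. Each list was tested with camera from limma 3.58.1 with a correlation between genes preset at 0.01, adjusted over the 23 lists of a comparison. Camera with an estimated correlation and fry were run beside it. Named genes are the 8 largest rises and 8 largest falls (5 for CoCl2 with acriflavine against control) among called genes with a mean of at least 5 CPM, a symbol that is not a clone name and no overlap between the groups compared. Chance alone separates 3 libraries from 3 in 10% of genes. Up to 3 called members of each list with a mean of at least 1 CPM were added, and CDH1, VIM, SNAI1, ZEB1, HIF1A, VEGFA and CA9 were always included. A list member named in 1 comparison could be given in the others. Of the genes that the rule selects, 1 among the largest rises in acriflavine against CoCl2 is not reported here.

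The steps were tested on simulated counts for the same 16143 genes, of which 200 were changed. For CoCl2 against control the test recovered 37.9% of the 1.5-fold changes, 83.3% of the 2-fold changes and 98.3% of the 4-fold changes, with 4 false calls. For CoCl2 with acriflavine against CoCl2 it recovered 48.3%, 81.0% and 100% with 5 false calls. For CoCl2 with acriflavine against control it recovered 41.4%, 86.9% and 100%, also with 5. The spread of the simulated counts was set by expression level alone, without gene-specific spread or a departure shared between libraries. These rates therefore need not hold for the real libraries.

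Libraries of 1 group were compared before they were averaged. The closest pair, CoCl2 replicates 2 and 3, had a chi-square per degree of freedom of 1.70, above the value of 1 that sampling noise gives, so all 9 libraries were used. The replicate numbers in the labels were checked for pairing through the correlation, over genes, of each library's deviation from its group mean. Control and CoCl2 libraries of the same number correlated at 0.636, 0.301 and 0.346, all over the criterion of 0.1 for pairing. Control 3 correlated more with CoCl2 2 (0.390) than with its own number, and control 2 correlated with CoCl2 3 at 0.279. Deviations within a group cancel out, so a shared departure of replicate 1 can by itself make numbers 2 and 3 correlate. The criterion thus shows replicate 1 of both groups departing together, but not whether numbers 2 and 3 are paired. The block values beside that comparison come from fits with the number as a replicate block, which gave 1189 higher and 1216 lower genes. Libraries with acriflavine did not pair with those of either other group, since their number 2 correlated at -0.139 with control and -0.118 with CoCl2.

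Alternatives were RLE size factors, library totals as the only scaling, the Wald test of DESeq2 1.42.0, limma-voom, no filter, a stricter filter of 1 CPM in 3 libraries, the replicate block, leaving out each library, fitting only the 6 libraries compared, and leaving out mitochondrially encoded genes. Chosen after seeing the data were the fit of the 6 control and CoCl2 libraries with the replicate block, the removal of replicate 1 of control and CoCl2, and a correction for transcript GC content with and without the replicate block. For the lists, members shared between lists were left out. Transcript GC content and length came from GENCODE transcripts on a later build, and no coordinates were taken from it. Figures were drawn with matplotlib 3.10.9.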

Results

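Gene expression was measured by RNA sequencing in PANC-1 pancreatic cancer cells under 3 conditions with 3 libraries each. Control cells were set against cells given CoCl2, a compound that stabilises hypoxia-inducible factor (HIF) and that the labels name as the inducer of an epithelial-to-mesenchymal transition (EMT). The third group received CoCl2 and acriflavine, which the series title presents as an inhibitor of that transition. Totals were 13684549 to 15906716 counts per control library, 13286339 to 15757145 per CoCl2 library and 14953732 to 15932220 per library with both compounds. Of 16143 genes tested, 9825 differed among the 3 groups. The first principal component held 71.1% of the variance and set the acriflavine libraries apart, between 71.7 and 99.96, from the other 6, between -49.6 and -33.3.

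The first comparison asked what CoCl2 changed in these cells. Genes of the hypoxia response rose. PDK1, a pyruvate dehydrogenase kinase, rose from 5.42 ± 0.448 to 73.4 ± 11.4 CPM (SD, n = 3 per group). The glycolytic enzymes ALDOC and HK2 had log2 fold changes of 3.67 ± 0.15 and 3.27 ± 0.20 (SE). HMOX1, which breaks down haem, rose from 218 ± 13.4 to 2058 ± 114 CPM. CDH1, which encodes E-cadherin, fell from 67.5 ± 1.22 to 31.0 ± 1.33 CPM, and COL1A1, a chain of type I collagen, fell from 197 ± 25.4 to 29.8 ± 6.64 CPM.

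Of 36 HIF target genes tested, 33 were higher, 0 were lower and 3 were not called, with a median log2 fold change of 1.68; adjusted over the list alone, 33 were higher. The list rose by camera (adjusted p = 6.8e-136 with the preset correlation and 0.00063 with an estimated one). VEGFA, the vascular growth factor, rose from 62.5 ± 1.51 to 213 ± 58.3 CPM. PPFIA4 had the largest log2 fold change of the named genes with counts in both groups, 4.13 ± 0.60, but its CoCl2 libraries varied widely (21.5 ± 18.1 CPM). CA9, a carbonic anhydrase, had no count in the 3 control libraries and reached 1.47 ± 0.224 CPM, at least 7.22-fold above the control floor of 0.203 CPM (3 counts per library). MIR210HG, the host transcript of a hypoxia-induced microRNA, had a log2 fold change of 3.57 ± 0.39, RORA one of 3.59 ± 0.46 and PFKFB4 one of 3.17 ± 0.15. With CA9 at its bound, the list's median was still 1.68. Of the 9 HIF pathway components tested, 3 were higher, among them EGLN1 (log2 fold change 1.64 ± 0.10) and EPAS1 (0.79 ± 0.10), and the list rose (adjusted p = 0.00049, and 0.034 with an estimated correlation), a call that ended when members shared with other lists were left out (adjusted p = 0.670). HIF1A itself had a log2 fold change of -0.35 ± 0.10 that was not called (adjusted p = 0.0503); with the replicate block it was (adjusted p = 0.0352), as it was by DESeq2 (0.0160), with library totals as scaling (0.0292), with the stricter filter (0.0492), without acriflavine replicate 2 (0.0472) or 3 (0.0458) and in the fit of 6 libraries with the replicate block (0.00149). Adjusted over the list alone, 4 components were higher and 3 lower.

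Glycolysis genes rose as well, with 18 of 21 tested members higher and 0 lower (19 higher adjusted over the list alone). Their camera adjusted p was 1.5e-61, and 0.0040 with an estimated correlation. NRF2 targets, the genes of the oxidative stress response, had 15 of 19 members higher (16 adjusted over the list alone), a median of 1.59 and an adjusted p of 8.5e-67, or 0.00054 with an estimated correlation. OSGIN1 rose from 11.1 ± 1.85 to 123 ± 2.05 CPM, and SLC7A11, the cystine transporter, had a log2 fold change of 2.48 ± 0.25. Of 23 genes of ATF4 and the integrated stress response, 17 were higher and 0 lower (19 higher adjusted over the list alone), with an adjusted p of 5.0e-38, or 0.00065 with an estimated correlation. STC2 and VLDLR had log2 fold changes of 2.67 ± 0.12 and 2.91 ± 0.25. ER chaperones followed with 5 of 19 higher (9 adjusted over the list alone), including HERPUD1 (1.43 ± 0.12) and HSPA5 (0.73 ± 0.11); the adjusted p was 2.3e-07, or 0.032 with an estimated correlation.

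SNAI1, a repressor of CDH1, rose from 13.2 ± 2.59 to 28.5 ± 3.37 CPM and was the 1 called member of the 10 EMT transcription factors tested. Adjusted over the list alone, 1 factor was higher and 1 lower. That list was not called (adjusted p = 0.95), its median of -0.16 lying below 0 while camera pointed up. ZEB1 (log2 fold change -0.17 ± 0.15, adjusted p = 0.55) and VIM (-0.19 ± 0.18, adjusted p = 0.59), which encodes vimentin, were not called; VIM was called when only the control and CoCl2 libraries were fitted with the replicate block (adjusted p = 0.00916). Among 25 epithelial markers, 5 were lower and 1 higher (8 and 2 adjusted over the list alone), with CDH1, EPCAM (-1.16 ± 0.17), CDH3 (-1.22 ± 0.19) and ST14 (-1.46 ± 0.23) among those that fell. Among 26 mesenchymal and matrix markers, 10 were lower and 1 higher (12 and 2 adjusted over the list alone). COL1A1, COL3A1 (-2.38 ± 0.29) and TAGLN (-1.88 ± 0.20) fell, and LOX, which crosslinks collagen and is also a HIF target, rose (2.64 ± 0.33). Both lists were lower by camera (adjusted p = 0.00012 and 4.1e-07), and neither call held with an estimated correlation (adjusted p = 0.17 and 0.15). Of 21 TGF-beta response genes, 9 were lower and 1 higher (10 and 1 adjusted over the list alone), including CCN1 (-1.31 ± 0.16) and LTBP2, which fell from 292 ± 49.5 to 136 ± 35.6 CPM. The adjusted p was 3.1e-05, and 0.14 with an estimated correlation. The other largest falls were EGR2 (-2.42 ± 0.34), PADI3 (-2.34 ± 0.34), MATN3 (-1.92 ± 0.31), MYL9 (-1.91 ± 0.31) and SPINT1 (-1.86 ± 0.21).

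Cholesterol synthesis genes were higher in 13 of 25 cases (20 higher and 1 lower adjusted over the list alone), including MVD (1.03 ± 0.15) and HMGCS1 (0.94 ± 0.13). Lysosome and autophagy genes were higher in 7 of 24 (9 higher and 1 lower adjusted over the list alone), including SQSTM1 (1.21 ± 0.13). Neither call, with adjusted p = 4.0e-11 and 0.00016, held with an estimated correlation (adjusted p = 0.15 for both). The other 11 lists were not called. The metal response had TFRC higher (1.26 ± 0.11) and SLC39A10 lower among 12 members (2 and 1 adjusted over the list alone; adjusted p = 0.157, and 0.0497 in the fit of 6 libraries with the replicate block). Of 23 p53 targets, 3 were higher and 1 lower (3 and 2 adjusted over the list alone; adjusted p = 0.593), among them GDF15 (1.01 ± 0.11). Of 32 G1/S genes, 4 were higher and 0 lower, also when adjusted over the list alone (adjusted p = 0.127). The G1/S list was called in the fit of 6 libraries with the replicate block (adjusted p = 0.0402) and without control replicate 2 (0.0438), control replicate 3 (0.0341) or CoCl2 replicate 1 (0.000207). It was also called with no filter (0.0435) and with replicate 1 of both groups removed (0.00362). Of 30 nuclear respiratory chain genes, 0 were called, also when adjusted over the list alone (adjusted p = 0.127); that list was called as lower without control replicate 1 (0.00897) or CoCl2 replicate 2 (0.0323), with library totals as scaling (0.0403) and with no filter (0.0268). Mitochondrially encoded mRNAs had 0 of 13 called, also when adjusted over the list alone (adjusted p = 0.955).

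Of 11 histone genes, 1 was higher and 1 lower (2 and 1 adjusted over the list alone; adjusted p = 0.593), and of 13 NF-kB and inflammatory genes ICAM1 was higher and CXCL1 lower (1 and 2 adjusted over the list alone; adjusted p = 0.681). Of 23 interferon response genes ISG20 was higher (1 adjusted over the list alone; adjusted p = 0.585), and of 23 ribosome biogenesis genes RRP12 was higher and UTP20 lower (1 and 1 adjusted over the list alone; adjusted p = 0.593). G2/M had UBE2C higher among 30 members (0 adjusted over the list alone; adjusted p = 0.681), and heat shock had HSPA4L lower among 12 (1 higher and 1 lower adjusted over the list alone; adjusted p = 0.955). The UTP20 call was lost without control replicate 2 (adjusted p = 0.0624) or CoCl2 replicate 2 (0.0569) or 3 (0.0512). Those of RRP12 and UBE2C were lost without any 1 library except CoCl2 replicate 1 and acriflavine replicate 2 (0.0556 to 0.144 and 0.0673 to 0.165), that of UBE2C also by limma-voom (0.0595). The HSPA4L call was lost without any 1 library except acriflavine replicate 1 (0.0518 to 0.146) and with replicate 1 of control and CoCl2 removed (0.168). Among these 11 lists, the median and the mean differed in sign for the inflammatory genes and the mitochondrial mRNAs.

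In all, 842 genes were higher and 808 lower, 288 and 268 of them by at least 2-fold. A correction for GC content with the replicate block gave 1435 higher and 1450 lower. With the replicate block 1216 were lower, with only the 6 libraries and the replicate block 2568 were higher and 2650 lower, and with library totals as scaling 715 were higher and 1147 lower, 38.4% higher against 51.0%. Without control replicate 2 the counts were 532 and 468, without control replicate 3 485 and 438, without CoCl2 replicate 2 556 and 507, and without CoCl2 replicate 3 529 and 435. Replicate 1 of control and of CoCl2 stood apart from replicates 2 and 3, with mitochondrial mRNAs at 3.48% of counts in control and 3.74% in CoCl2.

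**Figure D1:**
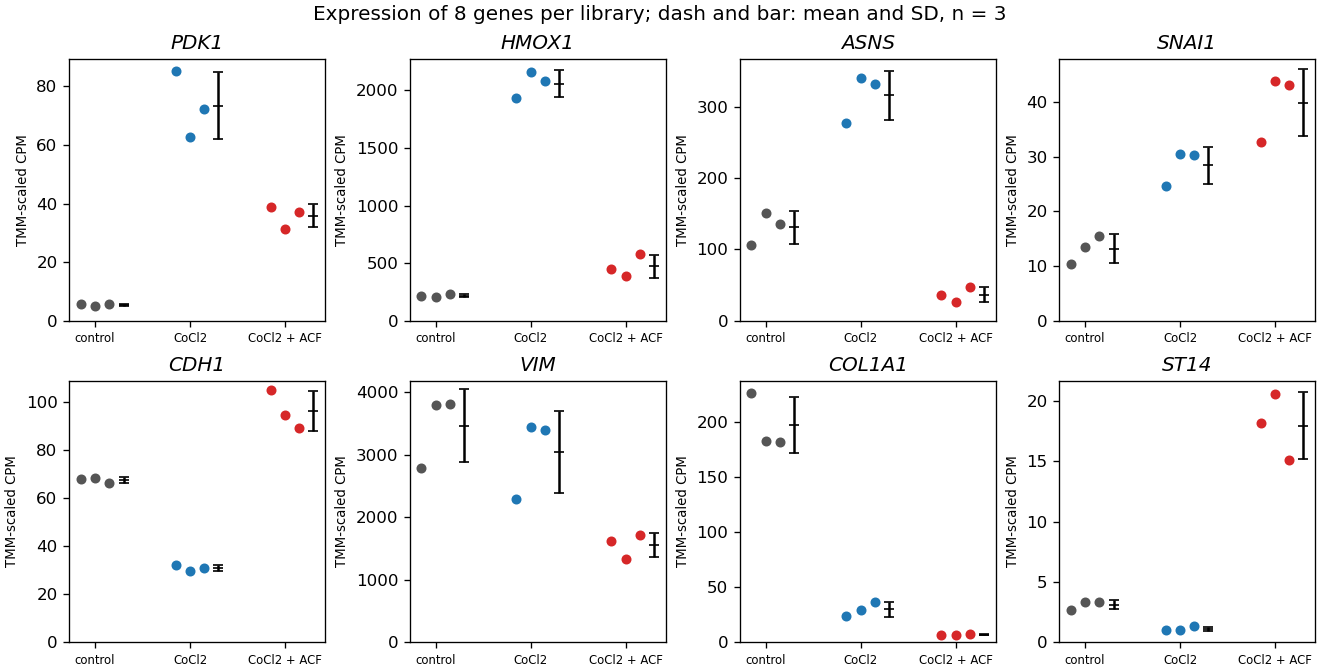
TMM-scaled CPM of 8 genes in each of the 9 libraries, by group, with points for libraries and a dash and bar for the mean and SD (n = 3). CDH1 fell with CoCl2 and lay at 96.2 ± 8.23 CPM with acriflavine added, above the control mean of 67.5, while COL1A1 fell at each step, to 7.03 ± 0.815 CPM.

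The second comparison asked what acriflavine changed in cells given CoCl2, the question named in the series title. Of all genes tested, 53.3% were called, so the number of called members of a list is to be read against that share. CDH1 rose from 31.0 ± 1.33 to 96.2 ± 8.23 CPM and VIM fell from 3038 ± 653 to 1557 ± 195 CPM. Of 25 epithelial markers, 14 were higher and 3 lower, with ST14 (log2 fold change 3.99 ± 0.21), OVOL1 (4.40 ± 0.47) and the desmosomal gene PKP2 (2.85 ± 0.25) showing the 3 largest changes. SNAI1 did not fall: it rose further, to 39.9 ± 6.18 CPM (log2 fold change 0.49 ± 0.16, adjusted p = 0.026), a call lost without CoCl2 replicate 1 (adjusted p = 0.0730), acriflavine replicate 2 (0.0684) or acriflavine replicate 3 (0.0910).

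The epithelial list was higher by camera (adjusted p = 0.00028, and 0.34 with an estimated correlation), with the counts 14 and 3 also when adjusted over the list alone. The 26 mesenchymal and matrix markers went both ways, with 9 higher and 12 lower, the same numbers adjusted over the list alone (adjusted p = 0.72). PDGFRB (-3.09 ± 0.32), LOX (-2.97 ± 0.34) and COL1A1 (-2.09 ± 0.18) fell, and FN1, which encodes fibronectin, rose from 3.06 ± 0.518 to 13.8 ± 1.38 CPM. Of 10 EMT transcription factors, 4 were higher and 1 lower (4 and 2 adjusted over the list alone). They included FOXC1 (1.11 ± 0.17), ZEB2 (1.11 ± 0.24) and TCF4 (-1.78 ± 0.36), and the list was not called (adjusted p = 0.28). ZEB1 was not called (-0.14 ± 0.15, adjusted p = 0.43). Of 21 TGF-beta response genes, 12 were higher and 3 lower (14 and 3 adjusted over the list alone), among them CCN2 (1.62 ± 0.24) and ID2 (2.29 ± 0.27); the list was not called (adjusted p = 0.084), but was without CoCl2 replicate 3 (0.0484), by limma-voom (0.0288) and with no filter (0.0166).

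HIF targets fell in 21 of 36 cases and rose in 6 (21 and 7 adjusted over the list alone), with a median log2 fold change of -0.49 and an adjusted p of 0.0029, or 0.46 with an estimated correlation. PFKFB4 fell from 117 ± 4.51 to 19.4 ± 3.30 CPM, DDIT4 had a log2 fold change of -2.59 ± 0.21 and CA9 one of -2.46 ± 0.42. VEGFA (-0.29 ± 0.16, adjusted p = 0.15) and HIF1A (0.19 ± 0.10, adjusted p = 0.13) were not called. EGLN3, a HIF prolyl hydroxylase, rose (1.15 ± 0.18), as did EPAS1 (0.90 ± 0.10), while ARNT2 fell (-1.42 ± 0.25). The 9 HIF pathway components had 3 higher and 4 lower, also when adjusted over the list alone (adjusted p = 0.98), with a median below 0 while camera pointed up. Glycolysis genes had 12 of 21 lower and 2 higher (14 and 2 adjusted over the list alone), with ALDOC at -3.71 ± 0.15, ENO2 at -2.09 ± 0.29 and PDK3 at -2.06 ± 0.25; the adjusted p was 3.5e-05, and 0.36 with an estimated correlation.

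The stress lists that had risen with CoCl2 were lower. NRF2 targets had 14 of 19 lower and 0 higher, also when adjusted over the list alone. HMOX1 fell to 474 ± 99.5 CPM, and ME1, malic enzyme, had a log2 fold change of -1.89 ± 0.09. Of 23 ATF4 and integrated stress response genes, 15 were lower and 4 higher, again the same adjusted over the list alone. PHGDH, the first enzyme of serine synthesis, fell from 201 ± 46.6 to 10.1 ± 5.03 CPM, ASNS, asparagine synthetase, from 316 ± 34.3 to 36.5 ± 10.5 CPM, and XPOT had a log2 fold change of -3.32 ± 0.22. ER chaperones had 12 of 19 lower and 0 higher (13 lower adjusted over the list alone), including HSPA5 (-1.36 ± 0.11). The adjusted p values of these 3 lists were 1.5e-06, 3.1e-06 and 0.00024, and 0.14, 0.14 and 0.16 with an estimated correlation. Cholesterol synthesis genes had 20 of 25 lower and 1 higher (21 and 1 adjusted over the list alone), including TM7SF2 (-3.06 ± 0.20) and DHCR7 (-2.14 ± 0.21). The adjusted p was 1.1e-10, and 0.25 with an estimated correlation.

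Mitochondrially encoded mRNAs had 12 of 13 members lower and 0 higher, also when adjusted over the list alone. Their median log2 fold change was -2.13, and MT-CO2, a subunit of cytochrome c oxidase, fell from 4817 ± 517 to 568 ± 158 CPM. The list's adjusted p was 1.3e-08, and 0.32 with an estimated correlation. In the same libraries the mitochondrial rRNAs MT-RNR1 and MT-RNR2, singled out after their values were seen, rose to 2.45 ± 0.546% of counts, and acriflavine replicate 2 stood apart with 3.08%. Of 30 nuclear genes of the respiratory chain, 6 were higher and 3 lower (4 and 3 adjusted over the list alone; adjusted p = 0.48), with NDUFB3 at 1.62 ± 0.14. Histone genes, many of whose mRNAs lack a poly-A tail, had 10 of 11 members higher and 1 lower, also when adjusted over the list alone, with H2BC11 at 3.45 ± 0.21, H4C8 at 3.23 ± 0.26 and H1-2 at 2.26 ± 0.13. Weaker poly-A selection in the acriflavine libraries could raise such mRNAs and was not excluded. Genes of G1/S and DNA replication had 23 of 32 higher and 1 lower, and genes of G2/M and mitosis 15 of 30 higher and 0 lower, in each case the same adjusted over the list alone. CCNE2 (1.52 ± 0.20), MCM10 (1.23 ± 0.15) and CDK1 (0.96 ± 0.15) were among them. The adjusted p values were 7.0e-10 for histones, 2.1e-06 for G1/S and 0.024 for G2/M; with an estimated correlation they were 0.14, 0.46 and 0.71. The G2/M call was lost without CoCl2 replicate 1 (adjusted p = 0.186) or acriflavine replicate 1 (0.0990), and with replicate 1 of control and CoCl2 removed (0.165). Heat shock genes had 8 of 12 higher and 0 lower, with HSPB1 at 1.58 ± 0.24 (adjusted p = 0.020, and 0.36 with an estimated correlation). Interferon response genes had 9 of 23 higher and 4 lower, with IFIT2 at 2.72 ± 0.12 and IFI35 at -1.71 ± 0.25 (adjusted p = 0.034, and 0.54 with an estimated correlation), a call lost without acriflavine replicate 1 (0.151) and by limma-voom (0.0677). The heat shock and interferon counts were the same adjusted over the list alone.

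The other lists were not called. Of 23 p53 targets, 5 were higher and 5 lower, also when adjusted over the list alone (adjusted p = 0.805), with the cell cycle inhibitor CDKN1A at 1.67 ± 0.17 and TP53INP1 at -1.36 ± 0.24. Of 12 metal response genes, 6 were higher and 2 lower, also when adjusted over the list alone (adjusted p = 0.357), with MT1A at 1.86 ± 0.41. Of 13 NF-kB and inflammatory genes, 4 were higher and 4 lower (5 and 4 adjusted over the list alone; adjusted p = 0.805), with CXCL8 at 1.68 ± 0.32 and NFKB1 at -1.97 ± 0.12. Of 24 lysosome and autophagy genes, 7 were higher and 8 lower (7 and 9 adjusted over the list alone; adjusted p = 0.357), with GABARAPL1 at 1.46 ± 0.15 and WIPI1 at -1.58 ± 0.11. Of 23 ribosome biogenesis genes, 8 were higher and 4 lower (8 and 5 adjusted over the list alone; adjusted p = 0.483), with WDR12 at -0.74 ± 0.11. The median and the mean differed in sign for the p53 and lysosome lists.

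Among the largest rises were those of NPPB (log2 fold change 7.47 ± 0.44), ANKRD1 (6.84 ± 0.40), KRT81 (5.93 ± 0.22), VSTM1 (5.93 ± 0.27), OLR1 (5.85 ± 0.40), DLL4 (5.79 ± 0.36) and CLDN6 (5.38 ± 0.29). In CoCl2, NPPB was at 0.102 ± 0.123 CPM and ANKRD1 at 0.145 ± 0.0134 CPM. Both lie below the floor of 3 counts per library, so the size of their changes is uncertain. NPPB encodes a natriuretic peptide, DLL4 a Notch ligand and CLDN6 a claudin. The largest falls besides PHGDH were those of SLC5A5 (-5.60 ± 0.40), ALDH1L2 (-4.46 ± 0.30), PLIN4 (-4.15 ± 0.24), FAAP100 (-4.08 ± 0.18), ANTKMT (-4.06 ± 0.34), BCAT1 (-3.87 ± 0.20) and RAB26 (-3.81 ± 0.20). SLC5A5 was at 0.106 ± 0.0675 CPM with acriflavine, also below that floor, so the size of its fall is uncertain. In all, 4138 genes were higher and 4463 lower, 1658 and 1889 of them by at least 2-fold, and 13 of the 23 lists were called. With an estimated correlation 0 lists were called, against 16 by fry, which tests whether a list's genes move one way on balance.

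**Figure D2:**
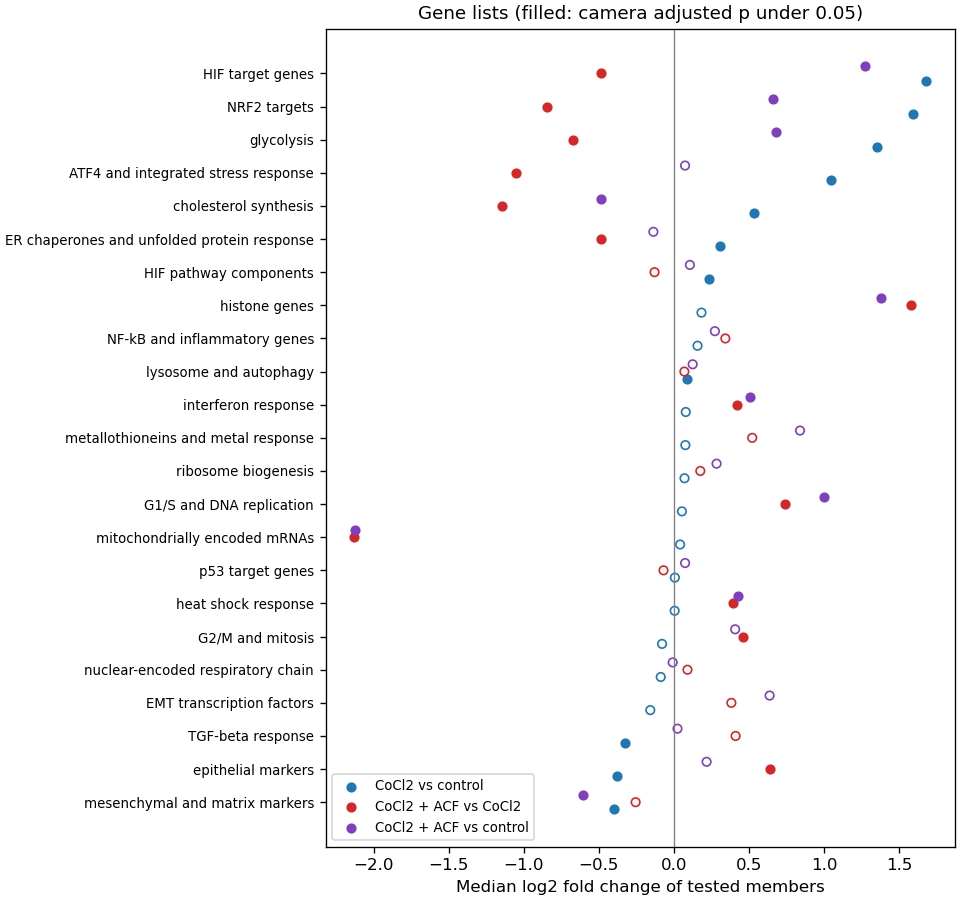
Median log2 fold change (x axis) of the tested members of each of the 23 gene lists (y axis) in the 3 comparisons, with filled points for lists whose camera adjusted p was below 0.05 with the preset correlation. HIF targets lay at 1.68 with CoCl2, at -0.49 with acriflavine against CoCl2 and at 1.27 with both compounds against control.

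**Figure D3:**
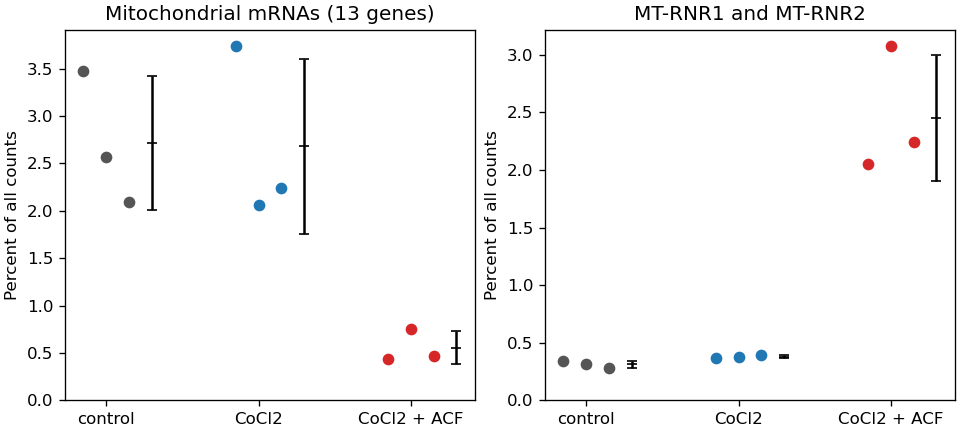
Percent of all counts taken by the 13 mitochondrially encoded mRNAs (left) and by the mitochondrial rRNAs MT-RNR1 and MT-RNR2 (right) in each library, by group, with a dash and bar for the mean and SD (n = 3). With acriflavine the mRNAs took 0.556 ± 0.175%, against 2.68 ± 0.922% with CoCl2 alone, and the rRNAs 2.45 ± 0.546%, against 0.380 ± 0.0135%.

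The third comparison set cells given both compounds against control cells. Of all genes tested, 57.0% were called, and list counts are to be read against that share. HIF targets lay mostly above control, with 27 of 36 higher and 3 lower (27 and 4 adjusted over the list alone). Their median log2 fold change was 1.27, or 1.18 with CA9 at its bound. VEGFA was at 174 ± 18.3 CPM against 62.5 ± 1.51 (log2 fold change 1.48 ± 0.17), and CA9 at 0.256 ± 0.117 CPM, at least 1.26-fold above the floor in control. CDH1 was higher than in control (0.51 ± 0.10), VIM lower (-1.15 ± 0.18) and SNAI1 higher (1.60 ± 0.17). ZEB1 (-0.31 ± 0.15, adjusted p = 0.091) and HIF1A (-0.16 ± 0.10, adjusted p = 0.21) were not called.

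The HIF target list was higher (adjusted p = 1.1e-15, and 0.19 with an estimated correlation). Of 26 mesenchymal and matrix markers, 15 were lower and 6 higher, the same adjusted over the list alone (adjusted p = 0.020, and 0.58 with an estimated correlation; by limma-voom 0.0641). Among them COL1A1 had a log2 fold change of -4.81 ± 0.19 and COL3A1 one of -3.69 ± 0.32. Of 25 epithelial markers, 10 were higher and 6 lower (11 and 6 adjusted over the list alone; adjusted p = 0.13). EPCAM (1.13 ± 0.16), ST14 (2.53 ± 0.18) and PKP2 (2.13 ± 0.24) were higher, and CDH3 was not called (-0.17 ± 0.18, adjusted p = 0.465). Of the 10 EMT transcription factors, 6 were higher and 2 lower, also when adjusted over the list alone (adjusted p = 0.31). NRF2 targets had 11 of 19 higher and 0 lower, also when adjusted over the list alone, with HMOX1 at 1.12 ± 0.14 (adjusted p = 0.0016, and 0.54 with an estimated correlation). Glycolysis genes had 11 of 21 higher and 3 lower (adjusted p = 0.00120, and 0.569 with an estimated correlation), a call that ended when members shared with other lists were left out (0.240); ALDOC was back near control (-0.04 ± 0.15, adjusted p = 0.827). Cholesterol synthesis genes had 16 of 25 lower and 1 higher (adjusted p = 0.00311, and 0.584 with an estimated correlation), and mitochondrially encoded mRNAs 12 of 13 lower and 0 higher (adjusted p = 1.75e-07, and 0.553 with an estimated correlation), with DHCR7 at -1.55 ± 0.20 and MT-CO2 at -2.85 ± 0.19. Histone genes had 9 of 11 higher and 0 lower (adjusted p = 6.51e-09, and 0.193 with an estimated correlation), with H2BC11 at 4.02 ± 0.22. Here too weaker poly-A selection was not excluded. G1/S genes had 25 of 32 higher and 1 lower (adjusted p = 3.26e-07, and 0.553 with an estimated correlation). Heat shock genes had 8 of 12 higher and 0 lower (adjusted p = 0.0357, and 0.553 with an estimated correlation), a call lost without control replicate 2 (0.0544). Interferon response genes had 12 of 23 higher and 5 lower (adjusted p = 0.0318, and 0.584 with an estimated correlation), a call lost without acriflavine replicate 1 (0.132), by limma-voom (0.0948) and with no filter (0.0614). Adjusted over the list alone, 13 mitochondrial mRNAs were lower, and the counts of these other lists were the same.

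The remaining 11 lists, besides the epithelial markers and EMT factors above, were not called. G2/M genes had 13 higher and 1 lower (adjusted p = 0.0852), and the list was called by limma-voom (0.0305), with no filter (0.0212) and without CoCl2 replicate 1 (0.0436) or acriflavine replicate 3 (0.0401). The metal response had 8 higher and 2 lower (0.130, and called with no filter, 0.0325), HIF pathway components 4 and 3 (0.153), ATF4 genes 10 and 7 (0.325), p53 targets 7 and 8 (0.619), inflammatory genes 6 and 6 (0.713), TGF-beta response genes 7 and 6 (0.861), nuclear respiratory chain genes 5 and 9 (0.953) and lysosome genes 9 and 7 (0.560). All of these counts were the same adjusted over the list alone. ER chaperones had 2 higher and 5 lower (1 and 5 adjusted over the list alone; adjusted p = 0.347), and ribosome biogenesis genes 8 and 5 (12 and 5 adjusted over the list alone; adjusted p = 0.347). The TGF-beta list's median lay above 0 while camera pointed down.

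The largest rises were those of ANKRD1 (6.73 ± 0.39), DLL4 (6.42 ± 0.38), KRT81 (5.92 ± 0.22), VSTM1 (5.74 ± 0.26) and NPPB. ANKRD1 was at 0.156 ± 0.0755 CPM in control, below the floor of 3 counts per library, so the size of its rise is uncertain. NPPB had 853 counts against 1 in control, a ratio of 824 with a 95% Poisson interval of 148 to 32592. That interval covers counting error only. The largest falls besides COL1A1 were those of SLC5A5 (-6.82 ± 0.38), FAAP100 (-4.83 ± 0.18), PLIN4 (-4.81 ± 0.24) and PCDH18 (-4.49 ± 0.28). SLC5A5 was at 0.106 ± 0.0675 CPM with both compounds, below the same floor, so the size of its fall is uncertain. In all, 4511 genes were higher and 4692 lower, 1898 and 2169 of them by at least 2-fold.

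Genes called with CoCl2 were then followed into the comparison with acriflavine. Of the 842 genes higher with CoCl2, 400 were lower again with acriflavine, PFKFB4, ALDOC and HMOX1 among them, and 172 rose further, among them SNAI1 and EPAS1. Of the 808 genes lower with CoCl2, 233 were higher with acriflavine, among them CDH1, EPCAM and CCN2, and 312 fell further, among them COL1A1 and COL3A1. Independent lists of these sizes would share 233, 216, 207 and 223 genes in that order. In 20 simulated data sets of unchanged groups that shared the CoCl2 libraries, 0 genes were called with CoCl2, so the simulations give no chance value for these 4 counts. The simulated counts had no gene-specific spread. The log2 fold changes of the 2 comparisons correlated across genes, which are not independent replicates, at -0.0554, with a covariance of -0.0310; the simulated values were -0.508 and -0.0321, a difference in covariance of 0.00104. Each group has 3 libraries, so the CoCl2 group could not be split into parts of at least 2, and part of any excess may come from the shared libraries. With the replicate block the genes that rose again numbered 352, those that rose further 291 and those that fell further 507. Library totals as scaling gave 351 that rose again, and GC correction gave 356 that rose again and 270 that rose further. GC correction with the replicate block gave 636 lower again, 458 that rose again, 373 that rose further and 585 that fell further. Called at 2-fold or more in both comparisons, these numbered 121, 83, 31 and 62. With no fold threshold and without control replicate 2, 135 genes rose again, 86 rose further and 185 fell further. In the same order, the counts were 130, 77 and 174 without control replicate 3, and 138, 78 and 140 without CoCl2 replicate 3. Without CoCl2 replicate 2, 90 rose further and 173 fell further. Of the 8601 genes called with acriflavine, 7484 (87.0%) were not called with CoCl2. Against control, 474 of the 842 genes were still higher in cells given both compounds, 252 were not called and 116 were lower.

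Markers of other cell types were read as levels, and the highest member of each list is named. Of 16 hepatocyte and HepG2 markers, 1 reached 1 CPM, TF, with 0.884 ± 0.151 CPM in control and a log2 fold change of 2.26 ± 0.31 with CoCl2. Of 11 blood cell markers 2 did, CD14 and SRGN, with SRGN at 2.40 ± 0.558 CPM in control, 8.98 ± 1.07 with CoCl2 and 41.1 ± 11.6 with both compounds. Among 8 endothelial markers ERG had the highest level (1.53 ± 0.255 CPM in control), and among 12 acinar and islet markers CEL did (2.60 ± 0.366 CPM with both compounds). Of 9 fibroblast markers 4 reached 1 CPM, and COL1A1 had the highest level; 4 of the 9 are also on another list.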

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

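Of the named genes, 1483 of 1530 values without 1 library and 1415 of 1423 values under the other settings kept direction and side of the threshold, and 0 changed direction. Of the lists, 582 of 621 and 583 of 644 did. Lists that changed direction were called in neither setting, and the cause of the changes below was not tested. The test among the 3 groups and the lists were not run with DESeq2. The median log2 fold change of all genes lay within 0.1 of 0 under each scaling, the farthest being -0.0764 in CoCl2 against control with library totals.

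With library totals as scaling, the direction changed in CoCl2 against control for heat shock (adjusted p = 0.980) and mitochondrial mRNAs (0.917), the respiratory chain was called (0.0403), and 351 genes fell and then rose. With limma-voom it changed for EMT factors in CoCl2 against control (0.947), HIF components in acriflavine against CoCl2 (0.907) and TGF-beta genes in acriflavine against control (0.970), where the mesenchymal (0.0641) and interferon calls (0.0948) were lost and G2/M was called (0.0305). In acriflavine against CoCl2, TGF-beta genes were called (0.0288) and the interferon call was lost (0.0677). With no filter, list calls were gained for G1/S (0.0435) and the respiratory chain (0.0268) in CoCl2 against control, TGF-beta genes in acriflavine against CoCl2 (0.0166), and the metal response (0.0325) and G2/M (0.0212) in acriflavine against control, where the interferon call was lost (0.0614). The direction changed for EMT factors in CoCl2 against control (0.650) and, in acriflavine against CoCl2, HIF components (0.852) and p53 targets (0.929). With the stricter filter it changed for inflammatory genes in acriflavine against CoCl2 (0.993) and the nuclear respiratory chain in acriflavine against control (0.990). With shared members left out it changed for HIF components in acriflavine against CoCl2 (0.845).

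With the replicate block 1216 genes were lower in CoCl2 against control, and 352 fell then rose, 291 rose further and 507 fell further. HIF components in acriflavine against CoCl2 (0.993) and the respiratory chain in acriflavine against control (0.970) changed direction. Apart from HIF1A, this block of 9 libraries ended or added no call of a named gene or list. With 6 libraries and the replicate block, 2568 genes were higher and 2650 lower. Without replicate 1 of control and CoCl2, 972 and 848 genes were called, and G2/M in CoCl2 against control (0.295) and HIF components in acriflavine against CoCl2 (0.901) changed direction. The G1/S list was then called in CoCl2 against control (0.00362), and G2/M lost its call in acriflavine against CoCl2 (0.165). With GC correction 356 genes fell then rose and 270 rose further. With GC correction and the replicate block 1435 genes were higher and 1450 lower in CoCl2 against control, and 636 rose then fell, 458 fell then rose, 373 rose further and 585 fell further. Called at 2-fold or more in both comparisons, the numbers were 121, 83, 31 and 62.

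With an estimated correlation 6 lists were called in CoCl2 against control, 0 in acriflavine against CoCl2 and 0 in acriflavine against control. Calls were lost for epithelial (adjusted p = 0.172) and mesenchymal markers (0.149) in the first comparison, for epithelial markers (0.339) and HIF targets (0.455) in the second, and for mesenchymal markers (0.584) and HIF targets (0.193) in the third.

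Leaving out 1 library at a time gave 485 to 1023 higher and 435 to 894 lower genes in CoCl2 against control. Of these, 268 to 496 rose then fell, 130 to 253 fell then rose, 77 to 213 rose further and 140 to 323 fell further. Adjusted p values of lists that changed direction in CoCl2 against control ran from 0.606 to 0.992 for EMT factors, 0.112 to 0.936 for G2/M, 0.484 to 0.993 for inflammatory genes, 0.484 to 0.993 for heat shock and 0.127 to 0.993 for mitochondrial mRNAs. In acriflavine against CoCl2 they ran from 0.887 to 0.995 for HIF components and 0.353 to 0.840 for inflammatory genes, and in acriflavine against control from 0.648 to 0.987 for the respiratory chain. At these depths the self-test, whose counts had no gene-specific spread, recovered 37.9% of 1.5-fold changes in CoCl2 against control. Changes of that size or smaller may therefore often have been missed.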

Other observations

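Genes of fatty acid synthesis were not among the lists fixed beforehand. FASN, fatty acid synthase, fell from 1540 ± 12.4 to 125 ± 45.8 CPM with acriflavine against CoCl2 (log2 fold change -3.62 ± 0.25), and FADS2, a desaturase, had a log2 fold change of -3.54 ± 0.22. Both were chosen after their values were seen, as was CYP1A1, an enzyme induced through the aryl hydrocarbon receptor, with a log2 fold change of 3.24 ± 0.38. A list of 15 other fatty acid genes was then written before their values were seen, to test the hypothesis that the group as a whole was lower. Of the 14 tested, 9 were lower and 0 higher, with a median log2 fold change of -0.72. SCD (-2.58 ± 0.18), ACSS2 (-2.25 ± 0.14), FADS1 (-2.27 ± 0.16) and SREBF1 (-1.61 ± 0.15) were among those that fell. The camera adjusted p was 2.0e-06, and 0.023 with an estimated correlation. Both were adjusted over only this list and the aryl hydrocarbon receptor list below. They cannot be set directly beside the adjusted p values of the lists fixed beforehand, which were adjusted over more lists. Whether the fatty acid list would be called with an estimated correlation when adjusted together with those lists was not tested. A list of 11 other aryl hydrocarbon receptor targets was written and tested in the same way. Of the 7 tested, 2 were higher (EREG and TGFA) and 2 lower (LPCAT2 and CYP1B1), with an adjusted p of 0.82. Their median of -0.28 lay below 0 by less than its spread of 0.41, so the test left this hypothesis undecided.

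Of the tests in the next 2 paragraphs, those of mitochondrial number, of normalization and of GC content were chosen only after the result was seen. With acriflavine the mitochondrial mRNAs fell while the mitochondrial rRNAs MT-RNR2 (log2 fold change 2.65 ± 0.17) and MT-RNR1 (2.69 ± 0.18) rose. Fewer mitochondria or mitochondrial genomes per cell would lower both kinds together, and the smaller rRNA change was a rise of 2.65. That rise prompted the test, and poly-A selection, discussed below, could also raise rRNA. It therefore does not decide whether fewer mitochondria or genomes lowered the mRNAs. If normalization were the cause, another scaling would have to bring the mRNAs near 0. With library totals as the only scaling their median was -2.11. That change of scaling moved the median of all genes only from -0.0196 to 0.0156 in acriflavine against CoCl2. It was too small to bring the mRNAs near 0, so this does not test normalization. Weaker poly-A selection in the acriflavine libraries could raise rRNA, and cannot be told apart from an effect of acriflavine, because 0 of the RNAs without a poly-A tail chosen for this test had enough counts; together 1809 such genes took 4.28 ± 1.37 CPM with acriflavine and 5.12 ± 3.85 CPM with CoCl2. Histone genes, many of whose mRNAs lack a poly-A tail, were higher in 10 of 11 cases and lower in 1 against CoCl2. Weaker poly-A selection could raise them too, so their rise does not tell these explanations apart. An effect of acriflavine on mitochondrial transcripts stays open as a hypothesis.

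Replicate 1 of control and of CoCl2 deviated together from the other libraries of their groups (correlation of deviations across genes 0.636). The deviation followed transcript GC content in both groups, with a Spearman rho across genes of -0.468 in control and -0.359 in CoCl2, so a GC-related library effect is a candidate explanation. Transcript length (rho 0.267 and 0.224) and the growth state of the cultures, read from the G2/M list (median deviation -0.188 in control and -0.594 in CoCl2), passed neither of the bounds set for them beyond their spread and remain open. The labels give no batch. With the GC trend removed and the replicate block, 1435 genes were higher and 1450 lower in CoCl2 against control.

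Other splits of the libraries were tested in the same way. For each comparison of 3 libraries with 3, the 10 possible splits are too few for a share under 0.05; the real split gave the most calls in each (1 of 10), with 1650, 8601 and 9203 genes, and the highest other split gave 0. Of the splits of control and CoCl2, 4 part all 3 of the replicate numbers, the real one included, and the others of these also gave 0. For the test among the 3 groups, 100 of the 280 splits were drawn and 1, the real one, gave 9825 genes or more, a share under 0.05. These splits did not take the replicate numbers of control and CoCl2 into account. The next gave 8046. The 4 splits that kept the acriflavine libraries together, the real one included, gave at least 6809, and the others at most 105. This points to a structure of the samples, so the small share rests mainly on the acriflavine libraries standing apart. For control against CoCl2, 4 splits are too few to exclude chance. For reversed genes, 2 of 100 labelled splits reached the real count of 633, the other with 6569, but this does not bear on chance, because the splits that mixed acriflavine libraries with others gave at most 32. With the acriflavine libraries kept as their own group, a test chosen only after the result was seen, the 20 labellings of the other 6 libraries as control or CoCl2 are too few for a share under 0.05. The real one gave 633, and the highest other, with control and CoCl2 exchanged as whole groups, gave 1046. The remaining labellings gave 0.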
